A study of Mus musculus with 10 samples.

How the data were processed

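RNA was sequenced from alveolar macrophages in 10 samples, 2 for each of 5 groups, per the labels. Per the labels' protocols, 100 pg of RNA from each sample were turned into cDNA with a SMARTer low-input kit and 18 cycles of PCR, and the cDNA was sheared by sonication, made into libraries with an Ovation Ultralow kit and sequenced on an Illumina instrument. Libraries of this kind carry no molecular identifiers and do not mark strand, so genes that overlap on opposite strands cannot be told apart, and at this input a transcript present in few copies can be missing from a library altogether.

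The deposited table holds FPKM values made by the authors for 45913 RefSeq transcripts in 10 columns, 1 per sample. Per the submitters' processing notes, Bowtie 1.1.2 and eXpress 1.5.1 are named with no role; eXpress divides reads that match several transcripts by a likelihood model, so values of near-identical genes are estimates. The genome build, the filters and any pooling are not given in the sources used here, and no coordinates are printed. The column sums of the deposited FPKM were 625660 to 668491, and were not scaled to a common total. All 10 columns matched a sample title, and 0 columns were left out. Some genes of the fixed lists, among them all mitochondrially encoded genes, are not analysed here: 615 of 648 list genes were found in the table. The genes Siglecf and Siglec5 are the same entry, named Siglec5 there.

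FPKM values were summed over the transcripts of each Entrez gene (26173 genes). Depth was estimated from the smallest values of genes with 1 transcript over 1.5 kb, using GENCODE M21 transcript lengths for 32449 transcripts. The commonest product of value and length within a fixed window was taken as 1 read. A depth outside the range set by that window could not have been found. This gave 9.35 and 9.17 M fragments for the conditional control samples, 9.35 and 9.35 for the normal-marker, 7.41 and 8.13 for the aberrant-marker, 9.35 and 8.85 for the wild-type and 8.40 and 8.70 for the germline knockout samples. These depths are approximate, because they rest on annotated and not effective lengths. Counts were not used, and no counting interval is given.

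The planned test, the rule for the genes named, the gene lists and most alternatives were chosen before the data were examined. The planned test was limma-trend on log2(FPKM + 1) with 2 replicates per group. Comparing the columns showed that the 2 samples of each group agree nearly within sampling noise, as repeat runs of 1 library or of 1 amplified cDNA would. The spread between them was taken to measure sequencing and not mice or libraries. The planned test was therefore not used for the comparisons, and each pair was averaged to 1 library. For the record, limma 3.58.1 with the columns taken as replicates called 8567 of 11336 genes between the 2 control libraries at an adjusted p threshold of 0.05; such a test compares libraries, not conditions. The gene set tests (camera, fry) and the Fisher test of overlaps planned with it were not run for the same reason.

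In place of the test a rule of size was used, chosen after the columns had been compared; its floor of 20 FPKM was planned and its 4-fold threshold was not. Genes with at least 1 FPKM in at least 2 columns entered (11336). A pseudocount of 1 FPKM was added before the log2. A gene was called where the libraries differed by at least 2 log2 units in the mean and in every choice of 1 run per library, and the highest library of the comparison had at least 20 FPKM. The demand on every run was made because some genes were filled in 1 run and empty in the other, though Tnp2 still passed it in the difference of the 2 effects: 4, 0, 7, 2 and 7 genes at 20 FPKM or more were 4-fold apart between the runs of the conditional control, normal-marker, aberrant-marker, wild-type and germline knockout libraries. Between runs, the median absolute log2 difference of genes at 20 FPKM or more was 0.0439 to 0.0509, against 0.411 to 0.823 between libraries.

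The genes named follow a fixed rule: Bach2; the 6 largest rises and 6 largest falls among called genes, leaving out predicted genes; up to 2 called genes of each fixed list; and 16 genes in every comparison whatever their change. For the difference between the 2 knockout effects and for the control comparison, 5 genes per direction were taken. Where that rule ranked by p, size was used instead. Some genes that it names are not reported here. Other list members were named after their values were seen. The fixed lists were alveolar macrophage identity, surfactant and lipid handling, cholesterol synthesis, alternative activation, inflammatory cytokines and chemokines, matrix and tissue remodelling, MHC class II and costimulation, interferon response, complement, lysosome, proliferation, haem, iron and oxidative stress, dissociation and immediate early response, mitochondrially encoded genes, sex check genes, and markers of monocyte-derived and interstitial macrophages, neutrophils, eosinophils with basophils and mast cells, T cells, natural killer and innate lymphoid cells, B and plasma cells, dendritic cells, lung epithelium, endothelium and stroma, and erythroid cells; 0 genes were in more than 1 list. For lists with at least 5 genes passing the filter, the median log2 difference was placed among 10000 random lists of the same size, each gene replaced by 1 of the 100 genes nearest in mean expression. A percentile below 2.5 or above 97.5 is called outside the random range, as a description of these libraries.

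The rule was tested on simulated runs made from the conditional control library, with 200 of 11336 genes, all well above the floor, changed, for the comparison of the aberrant-marker library with it. Of genes changed 6-fold 67 of 67 were called in the right direction, of genes changed 12-fold 66 of 66, of genes changed 3-fold 0 of 67, and of 11136 unchanged genes 0. The simulation drew sampling noise only, not the noise of low-input amplification. Of 40 simulated lists with no change 2 lay outside the random range, and of 40 lists shifted by 1 log2 unit 39 lay above it. The noise of each gene was drawn independently there, so these numbers do not hold for genes that vary together. Between the 2 control libraries, 3 of 20 lists lay outside the random range.

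Other settings tried were pseudocounts of 0.1 and 10, no filter, a filter of 10 FPKM, quantile normalization, median-ratio rescaling, a threshold of 2-fold, transcripts in place of genes, and leaving out each sample. Using the other control library as the reference, a floor of 100 FPKM, overlaps over genes at 20 FPKM or more and the limma fit were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.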

Results

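Alveolar macrophages, the resident macrophages of the airspace that clear surfactant and inhaled material, were profiled by RNA sequencing from C57BL/6 mice labelled as female and 16 weeks old. The question set by the labels was how macrophages change in mice in which Bach2, a transcription repressor of lymphocytes and macrophages, is lost. There were 5 groups. In the conditional line, Bach2 was floxed and Cre was driven by Cd4, a driver active in T cells. Macrophages of the conditional knockout need not have lost Bach2 themselves. From knockout mice of that line, macrophages whose surface markers looked like those of controls (the normal-marker library) and macrophages with aberrant surface markers (the aberrant-marker library) were profiled apart, beside macrophages of the conditional controls (the conditional control library). The normal-marker and aberrant-marker fractions were chosen by their surface markers. Levels of surface marker genes in them, and of genes that vary with these, may therefore follow from that choice. The other 2 groups were wild-type mice and germline Bach2 knockout mice. Each group had 2 samples in the labels. The values were FPKM, fragment counts scaled to transcript length and library size, and read counts were not used here. The low values fell on steps of 1 read that put the depth at about 7.41 M to 9.35 M fragments per sample, so that 1 read on a transcript of 2 kb was worth 0.0535 to 0.0675 FPKM.

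The 2 samples of a group agree nearly within sampling noise and were counted as 1 library. Their correlation on the log2(FPKM + 1) scale was 0.993 to 0.998, against 0.685 to 0.853 for samples of different groups. Of genes at 1 to 3 FPKM, 0.0960% to 0.196% were at exactly 0 in 1 of the 2 samples of a group, against 28.3% to 39.7% between groups. The median squared count difference over the count sum was 0.527 to 0.623 within groups at 1 to 10 FPKM, where reads drawn from 1 library give 0.455 and samples of different groups gave 71.9 to 106. All values below are therefore means of 2 sequencing runs of 1 library per group. No difference between groups has a replicate check, and no p-value is given. A gene is called higher or lower where the libraries were at least 4-fold apart on the log2(FPKM + 1) scale for the means and for every pairing of runs, with at least 20 FPKM in the higher library. This scale understates the change of low genes. The difference between the wild-type and the conditional control library serves as the yardstick. These 2 unaffected libraries are of different mouse lines and also differed in genes of the sex chromosomes, so the yardstick holds these differences together with library-to-library variation.

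Bach2 itself was near the limit of detection in every library. It was at 0.0186 FPKM in the conditional control, 0.0571 in the normal-marker, 0.0203 in the aberrant-marker and 0.0292 in the germline knockout library, and under the worth of 1 read in the wild type. The germline knockout value rested on 1 run (0.0584 FPKM), with far under 1 read in the other. The level of the target gene could therefore not check the genotype labels. Genes of the sex chromosomes differed from the labels. All mice were labelled female, but the Y-linked genes Eif2s3y (60.8 and 39.9 FPKM) and Ddx3y (24.2 and 7.18 FPKM) were present in the wild-type and germline knockout libraries, while Uty (7.78 and 0.0105 FPKM) and Kdm5d (1.55 FPKM and listed at 0) were present in the wild type and not in the germline knockout. Xist, the transcript of the inactive X chromosome of female cells, was at 3.75, 6.83 and 9.08 FPKM in the conditional control, normal-marker and aberrant-marker libraries and under 0.01 FPKM in the other 2.

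**Figure D1:**
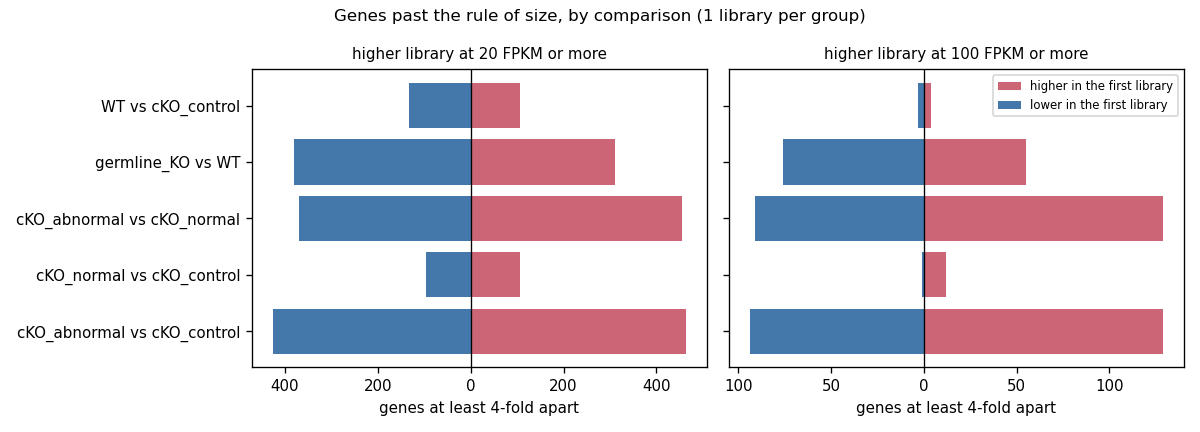
Number of genes at least 4-fold apart between 2 libraries (horizontal axis, genes higher in the first-named library to the right and lower to the left) for 5 comparisons of 1 library each (cKO_control, conditional control; cKO_normal, normal-marker; cKO_abnormal, aberrant-marker; WT, wild type; germline_KO, germline knockout), with the higher library at 20 FPKM or more (left panel) or 100 FPKM or more (right panel). With the floor of 100 FPKM, 7 genes separated the 2 control libraries and 13 the normal-marker library from its control, against 223 for the aberrant-marker library and 131 for the germline knockout.

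Aberrant-marker macrophages of the conditional knockout held far lower levels of many alveolar macrophage genes than the conditional control. Marco, a scavenger receptor, was at 224 FPKM in the control and 0.258 in the aberrant-marker library. Siglec5, the entry of the sialic acid receptor Siglec-F (Entrez 233186), went from 197 to 0.134 FPKM, the ribonuclease gene Ear1 from 966 to 2.27, the lipid droplet gene Cidec from 299 to 0.266, Perp from 164 to 0.270, and the neuropeptide gene Gal from 294 to 0.784. The largest rises were of Ccr7, the chemokine receptor of cells that migrate to lymph nodes, from 0.0937 to 1564 FPKM, Rgs1 from 0.0388 to 1034, Cxcl16 from 0.172 to 748, Aldh1a2, a retinoic acid synthesis enzyme, from 0.0767 to 655, and Ccl22 from 2.85 to 2002. Gadd45b was listed at 0 in the control and at 817 FPKM in the aberrant-marker library. In the wild type, Rgs1 was at 18.1, Gadd45b at 7.95 and Cxcl16 at 5.80 FPKM, so the size of their rises depended on the control used. Ccr7, Aldh1a2 and Ccl22 were at 0.0333, 0.0277 and 0.140 FPKM in the wild type. In all, 464 genes were higher and 426 lower among 11336 compared. Between the control libraries the numbers were 106 and 133.

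The fixed lists of genes moved apart. Of 33 measured genes of alveolar macrophage identity, 16 were lower and 0 higher, with a median log2 difference of -1.96 at percentile 0 of 10000 random lists matched on expression. Krt79 (477 to 13.8 FPKM), Krt19 (749 to 17.0) and Ear2 (3670 to 315) were among them, and Car4, a carbonic anhydrase, went from 308 to 43.3. Other identity genes did not pass the rule. Chil3, a chitinase-like protein abundant in these cells, was at 9166 and 8291 FPKM, Itgax (CD11c) at 253 and 124, Fabp4 at 104 and 83.7, and Pparg, a transcription factor required for the lineage, at 95.3 and 31.2. Of 29 genes of surfactant and lipid handling, 7 were lower and 3 higher (percentile 0.01). The lower ones included the lipoprotein lipase gene Lpl (530 to 85.1 FPKM) and the lysosomal lipase gene Lipa (371 to 63.9), and Scd1, a fatty acid desaturase, was higher (0.571 to 40.6). The cholesterol exporter Abcg1 was at 166 and 42.0 FPKM, short of the call. Of 39 proliferation genes, 7 were lower and 0 higher (median -2.52, percentile 0), with Ube2c at 37.1 FPKM and Ccnb1 at 23.4 FPKM in the control and both listed at 0 or far under 1 read in the aberrant-marker library.

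Transcripts of antigen presentation and of dendritic cells were high in the same library. Of 19 measured dendritic cell genes, 8 were higher and 0 lower (median 3.61, percentile 100), and 17 were at 1 FPKM or more in this library and 8 in the control, so the filter favoured genes present in it. The maturation marker Cd83 went from 18.5 to 1276 FPKM, Cst3 from 1063 to 13000, and Batf3 from 8.06 to 148, while Fscn1 (309 FPKM), the lectin gene Cd209a (109 FPKM) and the growth factor receptor Flt3 (37.4 FPKM) were listed at 0 in the control. Of 19 genes of MHC class II and costimulation, 8 were higher and 0 lower (median 2.40, percentile 100). H2-Aa went from 1389 to 6007 FPKM, H2-Oa from 0.594 to 29.9, Cd86 from 13.3 to 111, and Cd40 was listed at 0 in the control and at 136 FPKM in the aberrant-marker library. H2-Oa was at 10.5 FPKM in the wild type, so the size of its rise depended on the control used. Markers of T cells were present too. All 21 measured T cell genes were at 1 FPKM or more in this library and 1 was in the control, so nearly all passed the filter through this library, which sets the median of the list, and that median is not given. Of them, 4 passed the floor and the size threshold. Il7r reached 108 FPKM, Lat 37.9, Lck 29.6 and Cd3g 24.1, and Cd3e was at 17.7 FPKM, while all of these were under 0.1 FPKM in the control. Il7r was also at 41.7 FPKM in the germline knockout, as the only measured T cell gene at 1 FPKM or more there, so it did not mark T cells alone. The 5 measured genes of natural killer and innate lymphoid cells passed the filter mostly in the same way and none was called, with Nkg7 at 15.9 FPKM.

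Genes of alternative activation, the state induced by interleukin-4 and interleukin-13, included 14 higher and 1 lower of 28 measured (median 3.52, percentile 100). Which cells held the transcripts of this list and of those that follow was not tested. Ccl17 went from 4.58 to 1717 FPKM and the arginase gene Arg1 from 0.310 to 76.1, and Retnla (73.6 FPKM) and Ccl24 (37.4 FPKM) were listed at 0 in the control. Retnla, Ccl24 and C1qa, a gene of the monocyte-derived list, were at 0 in both control libraries and passed the filter through knockout libraries alone. How many members did so was not counted for the lists of this paragraph. Their medians and percentiles, here and in the other knockout comparisons, may be raised by the filter. Of 21 inflammatory cytokine and chemokine genes, 6 were higher and 1 lower (median 1.70, percentile 99.99). Ccl5 went from 0.498 to 516 FPKM and Ccl2 from 0.0755 to 75.5, whereas Il18 was lower, 409 against 23.6 FPKM. Il1b was at 15.2 and 0.158 FPKM and Tnf at 4.52 and 4.16 FPKM, both under the floor of 20 FPKM. Of 21 genes of monocyte-derived and interstitial macrophages, 6 were higher and 1 lower (median 1.18, percentile 99.85), including the complement component genes C1qb (1.01 to 375 FPKM) and C1qc (3.89 to 284 FPKM), C1qa (listed at 0 in the control, 193 FPKM) and the integrin gene Itgam (2.42 to 26.2 FPKM). Of 21 matrix and tissue remodelling genes, 3 were higher and 1 lower (median 0.92, percentile 99.53). The macrophage elastase gene Mmp12 went from 2.11 to 279 FPKM, and Pdgfa was listed at 0 in the control and at 29.1 FPKM. Of 33 interferon response genes, 3 were higher and 0 lower (percentile 99.74), among them Ifi47 (0.207 to 28.3 FPKM) and Usp18 (2.15 to 34.3 FPKM). Of 25 genes of tissue dissociation and immediate early response, 7 were higher and 0 lower (median 0.79, percentile 99.84), with Nr4a3 (159 FPKM) and Dusp2 (23.1 FPKM) listed at 0 in the control.

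The remaining lists lay within the range of random lists in this comparison. Of 29 genes of haem, iron and oxidative stress, 3 were higher, among them Gclc (10.1 to 197 FPKM) and Slc11a1 (4.28 to 127), and 3 lower, among them Gsr (255 to 31.1 FPKM), at percentile 11.99. The haem oxygenase gene Hmox1 was at 513 and 119 FPKM and missed the call because not every pairing of runs was 4-fold apart. Of 9 complement genes outside the C1q genes, C3ar1 was higher (listed at 0, 33.7 FPKM), and C5ar1 (433 to 23.0 FPKM) and Cfb (100.3 to 18.2 FPKM) were lower, at list percentile 22.5. Cholesterol synthesis had 1 higher of 22, the regulator Srebf2 (10.0 to 52.8 FPKM, but 22.8 FPKM in the wild type), at list percentile 92.9. Lysosome genes had 1 higher of 34, Cd63 (413 to 1838 FPKM, percentile 25.6). Of 11 lung epithelial genes, 1 was higher (Hopx, 2.41 FPKM against 100.3) and 3 lower, including Bpifa1 (32.0 FPKM in the control, listed at 0, and 4.00 FPKM in the wild type), at percentile 47.1. The 5 measured neutrophil genes held 1 call, Mmp25 (35.9 FPKM, under 1 read in the control), at percentile 35.6, and the 5 endothelial and stromal genes held 0 calls (percentile 76.8). Too few genes were measured to place the lists of eosinophils, basophils and mast cells (4 genes, with Alox5 lower, 192 to 17.1 FPKM), B and plasma cells (2 genes and 0 calls) and erythroid cells (1 gene, not called).

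**Figure D2:**
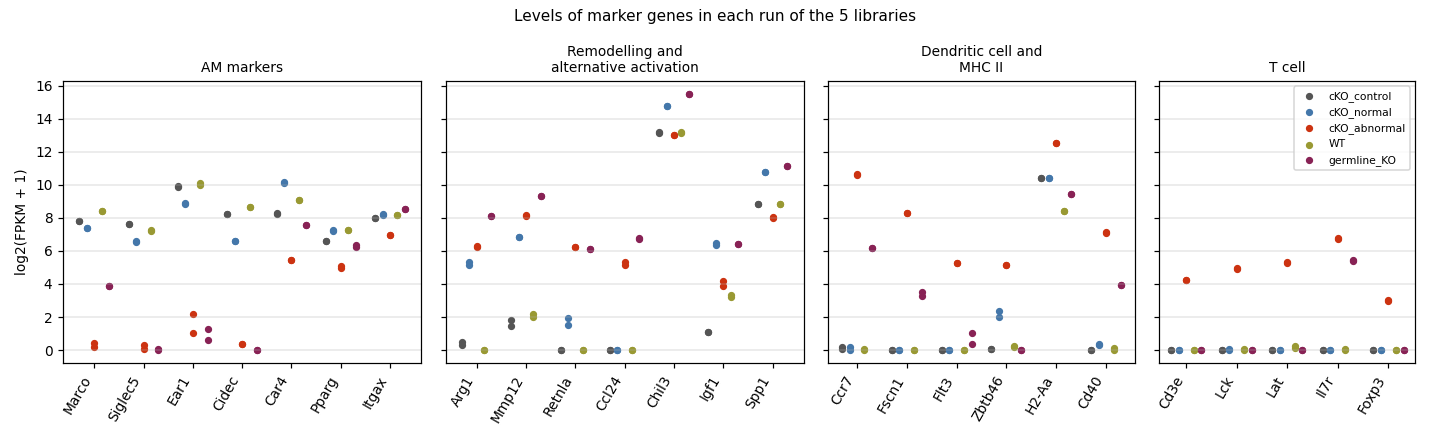
Level of marker genes on the log2(FPKM + 1) scale (vertical axis) in each of the 2 sequencing runs of the 5 libraries, with 1 colour per library and 1 point per run. Runs of a library mostly overlap. Marco, Siglec5, Ear1 and Cidec were low in the aberrant-marker and germline knockout libraries, Ccr7 reached 1564 FPKM in the aberrant-marker library, and Cd3e, Lck, Lat and Foxp3 were above 1 FPKM in that library only. Genes outside the fixed rule for naming were chosen for this plot after their values were seen.

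Normal-marker macrophages of the conditional knockout were separated from the conditional control by about as many genes as the wild type was. There were 106 genes higher and 95 lower, close to the 106 and 133 between the control libraries. The latter comparison also holds a difference in mouse line and in genes of the sex chromosomes, whereas the normal-marker and conditional control libraries are of 1 line and both had Xist and no Y-linked transcripts, so the 2 counts are not of like comparisons. Of the 33 alveolar macrophage identity genes, 0 were higher and 1 lower, Perp (164 to 27.2 FPKM), with a median log2 difference of 0.02 (percentile 87.8). Marco was at 224 and 168 FPKM, Siglec5 at 197 and 94.1, Itgax at 253 and 296, Pparg at 95.3 and 147, Fabp4 at 104 and 286, and Car4 at 308 and 1123, none of them called. This fraction was chosen for control-like surface markers. Its control-like levels of identity genes may in part follow from that choice. The largest rise was of Awat1, a wax synthase, from 1.05 to 187 FPKM, but it also differed between the 2 control libraries (32.0 FPKM in the wild type). Fbp1, a gluconeogenic enzyme, went from 0.587 to 123 FPKM, Rnase2a from 0.440 to 60.7, Igf1 from 1.12 to 84.2, Mmp12 from 2.11 to 115 and the phospholipase gene Pla2g2d from 0.326 to 43.3. Arg1 went from 0.310 to 36.9 FPKM. Chil3 was at 9166 and 27735 FPKM, below the 4-fold threshold. The largest falls were of genes at 25.0 to 41.9 FPKM in the control, Mis18a, Cd69, Hspa1a, Ppie, Ccnt1 and Appbp2. Cd69 was listed at 0 in the wild type too. Of genes apart from both control libraries at once, 44 were higher and 30 lower in the normal-marker library, against 341 and 241 in the aberrant-marker library. In the same trio with the normal-marker library, the wild type stood apart from the other 2 libraries by 32 genes higher and 35 lower, and the conditional control by 16 and 18.

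Between the 2 control libraries, 3 of 20 lists lay outside the random range, with medians of 0.34, -0.58 and -0.67. Of 20 lists placed for the normal-marker library, 6 lay above the central 95% of random lists, all with small medians. These were matrix and tissue remodelling (median 0.41, percentile 99.83, with 2 of 21 higher), lysosome (0.28, percentile 99.98, with 0 of 34 called), interferon response (0.27, percentile 98.9, 1 of 33 higher, Ifi47 at 23.9 FPKM), alternative activation (0.27, percentile 98.2, 1 of 28 higher, Arg1), cholesterol synthesis (0.43, percentile 98.6, 1 of 22 higher, Insig1 from 5.35 to 31.9 FPKM) and proliferation (0.32, percentile 98.1). For proliferation the only call went the other way, Bub1b, 29.6 against 1.39 FPKM. With a pseudocount of 0.1 in place of 1, the number of lists outside the range was 3. Single calls in other lists were C1qb (1.01 to 21.3 FPKM), Batf3 (8.06 to 45.9), Ahsp (50.5 to 338), C4b (0.114 to 24.8), Bpifa1 (32.0 to 4.37) and Napsa (50.1 to 10.8). Insig1 and Bpifa1 also passed the rule between the 2 control libraries (44.0 and 4.00 FPKM in the wild type). T cell genes had 0 calls. Retnla was at 2.35 FPKM, Ccl24 was listed at 0 in both libraries, Itgam was at 2.42 FPKM in the control and listed at 0, Il1b was at 15.2 and 17.5 FPKM, Tnf at 4.52 and 4.41, Hmox1 at 513 and 294, and Abcg1 at 166 and 125. With the wild type as the reference instead, a choice made after seeing the data, 319 genes differed, of which 74 were called in the same direction against the conditional control. With a floor of 100 FPKM, also chosen after seeing the data, 13 genes differed, 12 of them higher.

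The 2 populations of the conditional knockout differed from each other nearly as much as the aberrant-marker library differed from the control, with 456 genes higher and 369 lower in the aberrant-marker library. Its identity genes were again low, which may in part follow from the choice of the fractions by surface markers. Of 33, 17 were lower and 0 higher (median -2.22, percentile 0), including Marco (168 against 0.258 FPKM), Car4 (1123 against 43.3) and Pparg (147 against 31.2). Siglec5 (94.1 against 0.134 FPKM), Ear1 (476 against 2.27), Ugt1a7c (80.8 against 0.151 FPKM) and Ext2 (69.3 against 0.0264 FPKM) were among the largest falls, and Ccr7 (0.0641 against 1564), Cacnb3 (listed at 0, 444 FPKM), Tspan3 (0.657 against 654) and Fscn1 (listed at 0, 309 FPKM) among the largest rises. The lists above the random range were alternative activation (13 higher, 1 lower, median 2.64), inflammatory cytokines and chemokines (6 higher, 1 lower, median 1.49), MHC class II and costimulation (6 higher, 0 lower, median 1.92), dendritic cell (7 higher, median 2.93), and dissociation and immediate early (7 higher, median 1.54). T cell (4 higher) and natural killer and innate lymphoid genes (0 called) lay above it as well, but had mostly passed the filter through the aberrant-marker library. Below it lay identity, proliferation (9 lower of 39, median -2.25), surfactant and lipid handling (7 lower of 29, median -1.16) and lysosome (0 called, median -0.54, percentile 1.76). Among single calls, Itgam (listed at 0 in the normal-marker library), Mgl2 (listed under 1 read there, 285 FPKM), H2-DMb2 (4.28 to 118 FPKM), Gclc (6.14 to 197) and Usp18 (34.3 FPKM) were higher, and the transferrin gene Trf (1324 to 103 FPKM), Mmp8 (39.6 to 1.54), Sqle (32.3 to 6.00), Nsdhl (36.4 to 6.69), Birc5 (32.3 FPKM) and Ahsp (338 to 72.3) were lower. Retnla (2.35 to 73.6 FPKM) and Ccl24 (listed at 0, 37.4 FPKM) were higher too. Arg1 (36.9 and 76.1 FPKM), Mmp12 (115 and 279), Chil3 (27735 and 8291), Itgax (296 and 124), Fabp4 (286 and 83.7), Il1b (17.5 and 0.158), Tnf (4.41 and 4.16), Hmox1 (294 and 119) and Abcg1 (125 and 42.0) did not pass the rule.

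Germline knockout macrophages also held low levels of many identity genes, with high levels of remodelling and chemokine transcripts. Against the wild type, 310 genes were higher and 381 lower, but 341 were higher and 317 lower after median-ratio rescaling and 344 and 326 after quantile normalization, so the side with more genes depended on the scaling. Siglec5 went from 151 to 0.0247 FPKM, Marco from 339 to 13.5, Ear1 from 1055 to 0.964, and the fatty acid binding protein gene Fabp1 from 787 to 0.178. Cidec (405 FPKM), Gal (473 FPKM) and Fpr1, a formyl peptide receptor (467 FPKM), were listed at 0 in the knockout. The largest rises were of the retinol carrier gene Rbp4 (0.0711 to 684 FPKM), Ccl2, a chemoattractant of monocytes (0.0824 to 243), Fbp1 (0.0460 to 213), Fam20c (0.0508 to 163), Arg1 (listed at 0, 273 FPKM) and AA467197 (listed at 0, 234 FPKM). The rule also named Tnp2, a transition protein of sperm, at 1294 FPKM in the wild type and 0.0808 in the knockout, but its 2 runs in the aberrant-marker library read 0.284 and 1776 FPKM, so its estimate is uncertain.

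Of the 33 identity genes, 11 were lower and 1 higher in the germline knockout (median -1.38, percentile 0). The higher one was Chil3, at 9278 and 46574 FPKM. Itgax (289 and 365 FPKM), Pparg (153 and 79.3), Fabp4 (145 and 181) and Car4 (544 and 190) did not pass the rule. Of 21 matrix and tissue remodelling genes, 7 were higher and 1 lower (median 1.27, percentile 100), including Mmp12 (3.24 to 637 FPKM), Mmp14 (under 1 read in the wild type, 63.1 FPKM), Spp1 (455 to 2234) and Gpnmb (229 to 1633). Alternative activation had 9 higher and 0 lower of 28 (median 1.28, percentile 100), with Ccl7 (0.0285 to 136 FPKM), Retnla (69.5 FPKM) and Ccl24 (106 FPKM), the last 2 listed at 0 in the wild type. Inflammatory cytokines and chemokines had 9 higher and 1 lower of 21 (median 3.48, percentile 100). The lower one was Il18 (475 to 1.21 FPKM), and Il1b was at 9.77 and 31.0 FPKM and Tnf at 8.73 and 3.02, neither of them called. Monocyte-derived and interstitial macrophage genes had 7 higher and 2 lower of 21 (median 1.81, percentile 100), with C1qb (154 FPKM) and Itgam (99.3 FPKM) listed at 0 in the wild type. Lysosome genes had 3 higher of 34 (median 0.41, percentile 99.37), Cd63 (460 to 3052 FPKM), Lgmn (72.9 to 377) and Ctsl (187 to 843). Of 5 measured neutrophil genes 1 was higher, S100a8 (4.83 to 43.7 FPKM, list percentile 98.1).

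Proliferation genes had 6 lower and 0 higher of 39 (median -1.88, percentile 0), with Ube2c at 42.7 FPKM and Bub1b at 43.9 in the wild type against less than 1 read and 0.119 FPKM. Complement genes had 2 lower of 9 (median -1.98, percentile 0.06), C5ar1 (334 to 0.0259 FPKM) and Cfp (186 to 37.6). Dissociation and immediate early genes had 3 higher and 0 lower of 25, among them Socs3 (5.40 to 116 FPKM) and Ier3 (26.7 to 323), whereas the median of the list was -0.62 (percentile 1.82), so its calls and its median differed in sign. MHC class II genes had 1 lower of 19, H2-DMa (379 to 58.6 FPKM), with a median of 0. Il7r (41.7 FPKM) was the only called gene of 21 in the T cell list and Ccr7 (71.6 FPKM) the only one of 19 in the dendritic cell list. Within the random range also lay surfactant and lipid handling (percentile 3.50, with Lpl from 559 to 89.5 FPKM and Fabp5 from 335 to 1526), cholesterol synthesis (Cyp51 3.46 to 29.2 FPKM, but also 21.1 FPKM in the conditional control, a call between the 2 controls, and Sqle 36.1 to 7.55), haem, iron and oxidative stress (3 higher and 2 lower of 29, with Slc11a1 from 5.28 to 182 FPKM and Hfe from 0.431 to 40.0), interferon response (Oas1a 1.38 to 59.9 FPKM) and lung epithelial genes (Epcam 147 to 0.0360 FPKM, Hopx 2.57 to 31.6). Alox5 was at 185 FPKM in the wild type and 4.75 in the knockout. Hmox1 was at 278 and 192 FPKM and Abcg1 at 235 and 69.6, neither called. Rescaling the libraries by their median ratio moved the germline knockout differences by a median of 0.14 on the log2 scale over 6005 genes at 1 FPKM or more in all samples.

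The aberrant-marker and germline knockout libraries were compared with different control libraries, so their changes can be set side by side. Macrophages of the conditional knockout need not have lost Bach2, so the 2 knockout effects need not reflect the same loss. Across the 11336 genes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.305 and a Spearman correlation of 0.242. There were 108 genes higher in both, where independent lists of these lengths would share 12.7, and 116 lower in both, against 14.3. In opposite directions there were 4 and 5, against 15.6 and 11.6. Counted over the 3771 genes that reached 20 FPKM in both comparisons, a background chosen after seeing the data, the expected numbers were 12.1 and 24.2 in the same direction and 16.7 and 17.5 in opposite directions. Shared rises included Ccr7, Ccl17, Ccl22, Arg1, Mmp12, Retnla and Ccl24, and shared falls Marco, Siglec5, Ear1, Cidec, Gal, Perp, Fabp1, Krt79 and Plet1. In the germline knockout and aberrant-marker libraries, Ccr7 was at 71.6 and 1564 FPKM, Aldh1a2 at 41.6 and 655, and Tspan3 at 33.7 and 654. Arg1 (273 and 76.1 FPKM), Mmp12 (637 and 279) and Ccl24 (106 and 37.4) went the other way. Which cells held the shared transcripts was not tested. Dendritic cells in both libraries stay open as the source of a part of the shared rises. The difference between the 2 effects was at least 4-fold for 1039 genes, 560 of them with the larger value in the aberrant-marker comparison and 479 with the smaller, which turned to 508 and 554 after quantile normalization. Rgs1 stood 9.06 log2 units higher in that comparison, Ckb 8.83, Suox 8.69 and Eif4ebp2 8.27, and Tnp2, with its uncertain estimate, 20.02. In the other direction stood Nup93 (-8.31), Ear6 (-8.14), Pycrl (-7.61), Raet1d (-7.57) and Ivd (-7.26). Except for Rgs1 and Tnp2, these genes reached at most 21.6 to 41.6 FPKM in any library, close to the floor. Each of these values holds the difference of wild type minus conditional control as a part. Eif4ebp2, Tnp2, Nup93, Ear6, Pycrl, Raet1d and Ivd passed the rule between the 2 controls (4.30, 10.3, -4.51, -4.41, -3.35, -4.50 and -2.46), and Rgs1, Ckb and Suox were 3.42 log2 units or more higher in the wild type, with less than 20 FPKM in both controls, so these 10 genes are not a contrast of the knockouts alone. Of the 1039 genes, 156 also passed the rule between the controls. Among genes chosen after their values were seen, the value was lower in the aberrant-marker comparison for Arg1, Chil3, Itgam and Spp1 (-2.22, -2.47, -3.65 and -3.10) and higher for Cd40, Cd83 and Mgl2 (3.24, 5.85 and 2.86), of which the controls made up -1.77 for Itgam and 1.47 for Cd83. No difference between the effects has a test. Quantile normalization moved it by a median of -0.15 over 6005 genes at 1 FPKM or more in all samples.

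The yardstick comparison of the wild type with the conditional control held 106 genes higher and 133 lower. Among the largest rises in the wild type were Tnp2 (1294 FPKM), Csrp3 (732 FPKM), the Y-linked gene Eif2s3y (60.8 FPKM) and Sdhaf1 (39.9 FPKM). Csrp3 has an uncertain estimate as Tnp2 does, since it was under 1 read in 1 run and at 819 FPKM in the other run of the aberrant-marker library. The largest falls were Sco2, Bloc1s5, Ninj1, Akr1c13 and Cd69, at 30.6 to 37.4 FPKM in the conditional control and listed at 0 or under 1 read in the wild type. Differences of this size at such levels therefore occurred between unaffected libraries of different lines. Identity genes had 0 calls and a median of 0.34 (percentile 99.98), monocyte-derived and interstitial macrophage genes 0 calls and a median of -0.58 (percentile 1.68), and cholesterol synthesis genes a median of -0.67 (percentile 0.36).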

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

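The aberrant-marker and the germline knockout effects went in opposite directions for 9 genes, each called both times; the differences between the effects were not tested, since each group was 1 library, and these genes were singled out after the result was seen. The value in brackets after a gene is the log2 difference of the aberrant-marker comparison minus that of the germline comparison. Emd (4.29), Mcmbp (4.78), Gpatch4 (7.95) and Hyi (6.29) were higher in the aberrant-marker library than in its control. They were lower in the germline knockout than in the wild type. Manba (-6.32), Ivd (-7.26), Isoc1 (-5.08), Nup93 (-8.31) and 2310061I04Rik (-5.06) went the other way. Emd reached 77.8 FPKM, and the others reached 24.3 to 48.8 FPKM in their highest library. Of the 9, Gpatch4, Manba, Ivd, 2310061I04Rik and Nup93 also passed the rule between the 2 control libraries. Genes with opposite changes were fewer than independent lists would share, 4 against 15.6 in the first direction and 5 against 11.6 in the other (16.7 and 17.5 over genes at 20 FPKM or more in both comparisons).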

How the results depend on the processing

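The call of no named gene changed sign, but which side held more genes did change. It turned for the germline knockout with both scalings (344 higher and 326 lower with quantile normalization, 341 and 317 with median-ratio rescaling), for the difference of the 2 effects with quantile normalization (508 and 554), and with a 2-fold threshold for the aberrant-marker (975 and 1035) and normal-marker (379 and 458) libraries. It also turned for these 2 with limma on the runs (4767 and 4800, 3906 and 4739), for the normal-marker library against the wild type (155 and 164), and for the 2 controls with a pseudocount of 10 (16 and 13) and a floor of 100 FPKM (4 and 3). The counts of genes for aberrant-marker against control, normal-marker against control, aberrant-marker against normal-marker, germline knockout against wild type, the difference of the 2 effects, and the 2 controls fell with a pseudocount of 10 to 391, 38, 363, 254, 359 and 29. They rose with a 2-fold threshold to 2010, 837, 1979, 1713, 2319 and 902. With a floor of 100 FPKM, chosen after seeing the data, they were 223, 13, 220, 131, 150 and 7, and with limma on the runs as replicates, also chosen then, 9567, 8645, 9545, 9032, 9823 and 8567, with nearly as many genes between the controls as elsewhere. The wild type as the reference gave 319 for the normal-marker library. For the aberrant-marker library it gave 982, of which 582 were shared in direction with the 890, and the conditional control as the reference of the germline knockout gave 607, of which 367 were shared with the 691, so many calls depended on the control used. Lower thresholds, higher floors and larger pseudocounts change these counts by construction. A pseudocount of 0.1, filters, scalings, transcripts in place of genes and leaving out a sample kept each count within 1.5 times of its main value. The correlation of the 2 knockout effects was 0.255 with a pseudocount of 0.1, 0.404 with 10, 0.374 with a filter of 10 FPKM, 0.302 with quantile normalization, 0.302 with median-ratio rescaling and 0.409 over genes above the median level, and 0.2996 to 0.308 with single samples left out; the cause was not tested. Lists outside the random range for the normal-marker library numbered 3 with a pseudocount of 0.1, in place of 6. For the aberrant-marker library against its control they numbered 10 with a filter of 10 FPKM, in place of 13. The germline knockout had 8 with pseudocounts of 0.1 and 10, in place of 10. The place of single lists changed in 52 cases, over 23 pairs of list and comparison, and stayed in 933. Of 180 calls of named genes, 96 were kept with the floor of 100 FPKM, 146 with a pseudocount of 10, 174 with quantile normalization, 177 with median-ratio rescaling and 180 with a pseudocount of 0.1. The settings planned for the test alone (robust spread, groups in the fit, a term for the order of sample numbers, the correlation setting of the gene set test) were not run, nor were those for read counts, because with 1 library per group no spread between libraries exists and counts were not used. What limits these results is that number: leaving out a sample removes a sequencing run, not a library, and says nothing about another mouse.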

Other observations

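The tests of explanations in this part, and the overlap it opens with, were all chosen after the results were seen. A set of genes rose both in the normal-marker library against its control and in the germline knockout against the wild type, comparisons that share no library. There were 26 such genes, where independent lists would share 2.90, and 10 were lower in both, against 3.19 (2.502 and 4.53 over the 3651 genes that reached 20 FPKM in both comparisons). Besides Arg1, Mmp12, Igf1, Fbp1 and Rnase2a they included the bridging protein gene Mfge8 (10.8 to 135 FPKM in the conditional line and 13.9 to 423 in the germline line), the cell cycle regulator gene Rgcc (13.4 to 302 and 60.1 to 394), Ecm1 (10.1 to 139 and 0.189 to 91.3), Wfdc17 (69.4 to 484 and 10.3 to 1643) and C1qb. Spp1 (457 and 1756 FPKM in the conditional line, 455 and 2234 in the germline line) and Chil3 passed the rule in the germline comparison alone, and Trem2 (50.6 and 189.6, then 70.9 and 252 FPKM) in neither. Across genes, the correlation of the 2 sets of log2 differences was 0.120.

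A candidate explanation of this overlap is a carry-over of aberrant-marker cells into the normal-marker fraction. If so, 1 share would hold for all genes high in the aberrant-marker library. The 129 genes higher there with at least 100 FPKM had in the normal-marker library a median of 0.463% of their rise over the control (upper quartile 7.75%), below the 5.42% or more that the 19 pattern genes among those higher there would need, with Ccr7 at 1564 FPKM in the aberrant-marker and 0.0641 in the normal-marker library, which argues against carry-over of whole aberrant-marker cells. Genes that drop in and out of low-input libraries would overlap as much in opposite directions, but the excess over independent lists was 8.97 for genes higher in both and at most 1.12 in opposite directions (10.4 and at most 0.916 over genes at 20 FPKM or more). Of the 26 genes, 12 were higher in the normal-marker than in the aberrant-marker library, among them Igf1 (84.2 and 15.4 FPKM). A subset of aberrant-marker cells could supply these 12 only if it held far more of them than the aberrant-marker library as a whole. Such a subset, or a partial change within the normal-marker cells of the knockout, was not tested and stays open as the source. With 1 library per group, a difference between mice remains untested too.

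The aberrant-marker library held dendritic cell and T cell transcripts and few macrophage markers. Control-like macrophages left in that fraction may be the source of its remaining macrophage transcripts, but Marco, Siglec5, Cidec and Ear1 kept at most 0.235% of their control level, while the median over 31 identity genes was 21.8% and Chil3 kept 90.5%, which argues against them as the only source. T cells in the fraction remain a candidate source, since 21 of 28 T cell genes were at 1 FPKM or more, including Cd3d (16.2 FPKM), Cd3e, Foxp3 (7.02 FPKM) and Ctla4 (14.6 FPKM), against at most 1 in any other library (Il7r at 41.7 FPKM in the germline knockout, Cd4 at 5.13 FPKM in the normal-marker library). Dendritic cells in the fraction are likewise a candidate, since 15 of 19 measured dendritic cell genes, with Flt3 and Zbtb46 (34.2 FPKM), were highest in this library. Macrophages that themselves express these genes were not tested and stay open, and the labels used here name no gate that would remove other cells.

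The wild-type and germline knockout libraries, labelled female, held some Y-linked transcripts and almost no Xist. Reads of the X-linked copies Eif2s3x and Ddx3x may in principle be counted on the Y-linked genes, but the ratio of Y-linked to X-linked copies was 0.970 or more in these 2 libraries and at most 0.00127 in the conditional ones. A minor share of male RNA in female samples would leave Xist in place, and it was at most 0.0632% of its lowest conditional level. That level was 3.75 FPKM, and transcripts this low can be missing from a library of this input. The absence of Xist alone therefore does not decide this. Cells of male mice in both libraries, against the label, remain a candidate explanation, with Eif2s3y and Ddx3y at 7.18 FPKM or more in both. In the germline knockout, however, Uty was at 0.0105 FPKM and Kdm5d was listed at 0, against 7.78 and 1.55 FPKM in the wild type, so the Y-linked genes did not all show it there. The X-linked copies of these genes, Kdm6a (0.0879 FPKM) and Kdm5c (0.317 FPKM), were low in the germline knockout too. In the wild type Kdm6a was as low (0.0907 FPKM) with Uty present, and Kdm5c was at 2.58 FPKM. Since low transcripts can be missing from a library of this input, the absence of Uty and Kdm5d does not decide the question.

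A few entries of the table switched between the 2 runs of the same library. In the aberrant-marker library Tnp2 (0.284 and 1776 FPKM) and Csrp3 (listed under 1 read and 819 FPKM) were empty in the run in which Gm5941 (1524 FPKM) and Gm20736 (672 FPKM) were filled, and the other way round. In the germline knockout Csrp3 and Gm5941 (815 against 1807 FPKM) alternated in the same manner.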
